A study of Pseudomonas veronii 1YdBTEX2 with 12 samples.

How the data were processed

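Cultures of Pseudomonas veronii 1YdBTEX2 were measured on 12 custom 1-colour microarrays, on which Cy3-labelled cDNA made from total RNA was hybridised. Per the labels, cells growing on succinate were left for 30 min in control medium (5 arrays), in medium with NaCl at a solute potential of -0.5 MPa (4 arrays) or in medium with PEG8000 at a matric potential of -0.5 MPa (3 arrays). The labels call the replicates independent, and they describe all 5 control arrays as the control of the solute stress. Groups and replicate numbers were taken from the sample titles.

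Per the file headers, the arrays were scanned and extracted by the authors with Agilent Feature Extraction 10.7.3.1. The deposited spot values are intensity values on a linear scale, background-subtracted per the file headers and not normalized between arrays. Other deposited columns are flags that the extraction software set per the file headers, such as a spot being well above background, saturated or an outlier. A further deposited table holds log2 values for 5497 genes, and its row medians lie within 5e-07 of 0, so each gene was centred on its median over the 12 arrays. In that table each of the 12 columns correlated best with the scanner values of its own array (Pearson r across genes from 0.74 to 0.97, lowest for NaCl replicate 3), which settles its direction. The SD of a column was 0.80 to 1.01 times that of the log2 scanner values of its array (0.96 to 1.01 for the control arrays), close to the ratio of 1 that log2 values would have without further normalization. The table was therefore read as log2. Its column medians lie between -0.026 and 0.0093. How it was normalized between arrays is not given in the sources used here.

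Of 62976 spots, 61647 carry a bacterial identifier, which stand for 40617 probes and 6358 genes (6353 identifiers of the form YdB-peg and 5 of the form YdB-rna). A gene had a median of 5 probes and at most 93, and 798 genes had 1. Spots flagged as outliers were dropped, and 0 spots were saturated. The log2 intensity minus the array's 75th percentile over bacterial spots was averaged over the spots of a probe and then over the probes of a gene. Genes were kept where at least 1 probe was well above background on at least 3 arrays, which left out 10 genes and kept 6348. The arrays' number limits the precision, with a median standard error of 0.11 to 0.13 log2 across genes.

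All 12 arrays entered 1 linear model with 3 group means in limma 3.58.1 under R 4.3.3 (lmFit and eBayes, two-sided). P-values were adjusted by the Benjamini-Hochberg method over the 6348 genes of each comparison. A gene was called at an adjusted p under 0.05, and genes with a change of at least 2-fold were counted apart. Genes called under both stresses were set beside 100 simulations of unchanged groups against the same control arrays, beside independent lists, and beside 20 assignments of the control arrays to the stresses.

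On simulated data with 200 of the 6348 genes changed, a change of 1 log2 unit was recovered for 97% of the changed genes in NaCl against control. The share was 94% in PEG against control and 89.6% in PEG against NaCl. A change of 0.5 log2 was recovered for 65.7%, 59.7% and 43.3% of them. False calls made up 2.8%, 3.4% and 6.1% of all calls. The simulated genes varied independently and had no shift with gene level, so these shares need not hold for the real counts.

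The files do not pair the identifiers with gene names or products. The rule for the genes named was therefore its stated substitute, the 2 identifiers that rose most and the 2 that fell most in each comparison, among called genes whose arrays of one group all lie above those of the other. The 24 gene lists fixed for this work had 0 members among these identifiers, so no list was tested. The limma tests of the 3 comparisons on all 12 arrays, the count of genes changed by both stresses and the naming rule were chosen before the data were examined. A run is a set of at least 3 genes with consecutive identifier numbers, each changed at least 2-fold in the same direction. The analysis by runs was added after the data were seen.

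Arrays lay on 2 slides, each with its own scan. Slide 1 held control replicates 1 to 3 and the 3 PEG arrays, and slide 2 held control replicates 4 and 5 and the 4 NaCl arrays. An alternative was another background correction (normexp with an offset of 50 on the median spot signal, also scaled to the array's 75th percentile). Other alternatives were quantile normalization, median centring and other filters on dim probes. Further ones were the median over probes, the authors' log2 table, the slide as a block, the replicate number as a block, fits of 2 groups, array weights, another variance prior and each array left out in turn. The planned correction of the mean spot signal was not run. Replicate numbers did not pair the arrays of different groups.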

Results

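Transcript levels of Pseudomonas veronii 1YdBTEX2, a bacterium of interest for the bioremediation of soil, were measured after 30 min of solute stress (NaCl) or matric stress (PEG8000). There were 5 control arrays, 4 NaCl arrays and 3 PEG arrays, with 6348 genes tested. The median spot intensity was between 267.1 and 684.8 across arrays, and 90.4% to 99.8% of the spots were well above background. Within groups, the median SD of a gene was 0.11 log2 in control, 0.17 in NaCl and 0.18 in PEG. Levels below are log2 intensities relative to the 75th percentile of the array, changes are log2 differences with the standard error of the limma fit, and adjusted p-values are Benjamini-Hochberg values from that fit. Genes are given by the identifiers of the arrays, which the files do not pair with names.

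The first comparison asked how the cells responded to NaCl. The strongest rise was that of YdB-peg3255, from -2.49 ± 0.16 in control (SD, n = 5) to 1.83 ± 0.12 in NaCl (SD, n = 4), a change of 4.31 ± 0.12 (SE) or 19.9-fold (limma adjusted p = 5.56e-11). YdB-peg3657 rose by 4.30 ± 0.15 (SE), or 19.6-fold (adjusted p = 3.94e-10), from -3.96 ± 0.13 to 0.34 ± 0.39. It forms a run with 2 genes of consecutive numbers, and the 3 rose by 3.55 to 4.30. A further run of 4 genes rose by a mean of 3.00, and another of 3 genes by a mean of 2.72. YdB-peg3995 fell most, with a change of -2.38 ± 0.16 (SE, adjusted p = 2.63e-07), and the 4 genes of its run changed by -1.19 to -2.38. YdB-peg1455 changed by -1.62 ± 0.10 (SE, adjusted p = 1.12e-07), in a run of 4 with a mean change of -1.40.

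These 4 named genes were well above background on every control and NaCl array, and all their probes changed in the same direction. In all, limma called 3891 of 6348 genes (61.3%) in NaCl against control, 2914 higher and 977 lower. Of these, 269 were at least 2-fold higher and 45 at least 2-fold lower, and 22 were at least 4-fold higher against 1 at least 4-fold lower. The median gene stood 0.23 log2 higher in NaCl, and relative to that shift 124 genes were at least 2-fold higher and 106 at least 2-fold lower. Relative to the median gene, YdB-peg3255 changed by 4.08, YdB-peg3657 by 4.06, YdB-peg3995 by -2.61 and YdB-peg1455 by -1.86. The shift itself differed with gene level, so these values and counts are not relative to genes of like level.

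The rise was tied to gene level. Among the 1587 dimmest genes 1318 were called higher and 6 lower, with a median change of 0.64, whereas among the 1587 brightest 212 were higher and 623 lower, with a median change of -0.16. NaCl replicates 1 and 3 showed it most, with median changes of 0.94 and 0.85 in these dimmest genes, against 0.30 and 0.43 in replicates 2 and 4. With each array centred on its median, 1916 genes were called higher and 1805 lower, after quantile normalization 1276 higher and 1476 lower, and with normexp 3122 higher and 1115 lower. Among called genes the share higher was 74.9% with the 75th percentile, 51.5% with median centring, 46.4% with quantile normalization and 73.7% with normexp. Median centring and quantile normalization bring the median change near 0 by construction. Normexp values were also scaled to the 75th percentile of each array, so their share is no independent check of that scale. All 59 genes in runs kept their direction and their call under median centring, quantile normalization and normexp. They were picked for called changes of at least 2-fold in these data, so this was likely. With the 2-fold limit applied anew, 56, 59 and 39 genes lay in runs under these 3 settings. With the slide as a block, 2292 genes were called higher and 657 lower, and within slide 2 (2 control and 4 NaCl arrays) 1605 higher and 505 lower. The changes with the block were 4.32 for YdB-peg3255, 4.37 for YdB-peg3657, -2.38 for YdB-peg3995 and -1.79 for YdB-peg1455. All NaCl arrays lay on slide 2, so the fit within slide 2 gives the same changes by construction and is no second check of them.

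**Figure D1:**
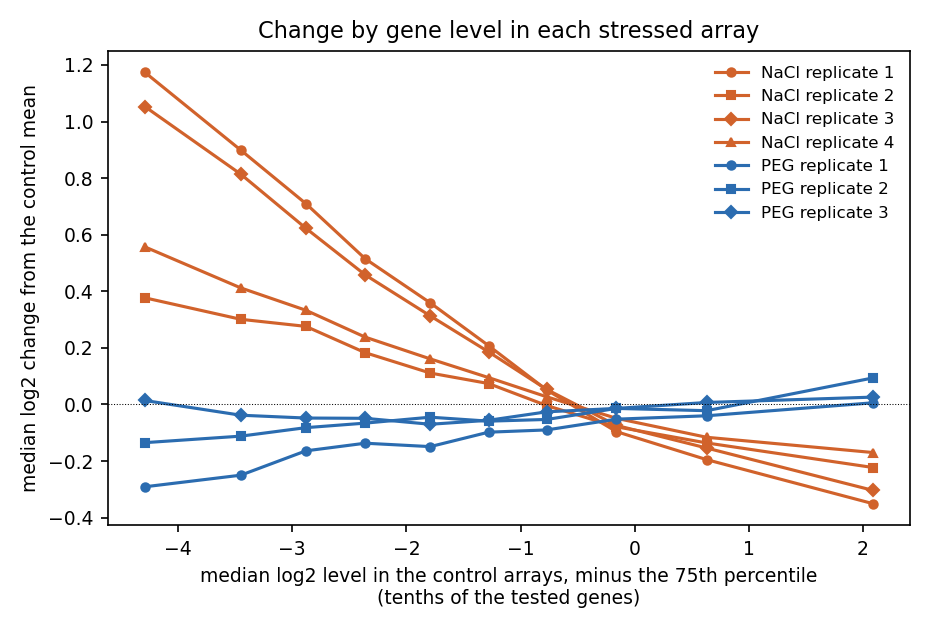
Median log2 change from the control mean in each NaCl and PEG array (vertical axis), for 10 groups of tested genes ordered by their level in the control arrays (horizontal axis, log2 relative to the 75th percentile). In the dimmest group, NaCl replicate 1 stands at 1.17 and NaCl replicate 3 at 1.05, while the PEG arrays lie between -0.29 and 0.01.

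The second comparison asked how the cells responded to PEG. YdB-peg3674 rose most of all genes in any comparison, from -4.29 ± 0.13 in control (SD, n = 5) to 2.33 ± 0.04 in PEG (SD, n = 3), a change of 6.62 ± 0.16 (SE) or 98.3-fold (limma adjusted p = 1.35e-11). YdB-peg3288 rose by 5.25 ± 0.13 (SE), or 38-fold (adjusted p = 1.35e-11), from -1.97 ± 0.23 to 3.27 ± 0.12. It lies in a run of 6 genes that rose by 1.23 to 5.25, with a mean of 4.33. Runs of 3 and 4 genes that were also higher in NaCl rose by means of 2.74 and 2.38 in PEG. Among falling genes, YdB-peg213 changed by -3.16 ± 0.39 (SE, adjusted p = 4.98e-05) and YdB-peg214 by -2.89 ± 0.39 (SE, adjusted p = 9.7e-05).

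YdB-peg213 and YdB-peg214 are members of a run of 8 genes that changed by a mean of -2.23 in PEG. The control arrays themselves differed in this run. Its mean level was -1.42 in control replicate 3, between 0.37 and 1.22 in the other control arrays, and between -1.97 and -1.66 in the PEG arrays. Without control replicate 3 the change of YdB-peg213 was -3.41 and that of YdB-peg214 was -3.15. Without control replicate 5 the changes were -2.97 and -2.67. In these 2 genes control replicate 1 was about as low as control replicate 3. The levels were -0.61 and -0.66 for YdB-peg213, and -2.49 and -2.6 for YdB-peg214. Both falls and rises in PEG came in runs. Of 175 genes at least 2-fold lower, 78 lay in 17 runs, and of 80 genes at least 2-fold higher, 37 lay in 10 runs. A group of 4 runs within a short stretch of identifier numbers fell by means of -1.82, -1.83, -2.09 and -2.14, and the same runs changed by means of -0.85, -0.75, -1.18 and -1.11 in NaCl, with all of their members called lower there too.

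In PEG against control limma called 1982 genes (31.2%), 812 higher and 1170 lower, and 16 were at least 4-fold higher against 28 at least 4-fold lower. The median gene changed by -0.08. Median centring gave 1043 genes higher and 1010 lower, a share of 50.8% higher against 41% with the 75th percentile, and normexp gave 51.3%. The genes changed at least 2-fold then numbered 87 higher and 154 lower with median centring. All 115 genes in runs kept their direction and call under median centring, quantile normalization and normexp, which was likely for genes picked by large changes. With the 2-fold limit applied anew, 114, 105 and 85 genes lay in runs under these settings. With the slide as a block, 609 genes were called higher and 951 lower, and within slide 1 (3 control and 3 PEG arrays) 552 higher and 940 lower. The changes with the block were 6.60 for YdB-peg3674, 5.12 for YdB-peg3288, -2.73 for YdB-peg213 and -2.46 for YdB-peg214. All PEG arrays lay on slide 1, so the fit within slide 1 gives the same changes by construction and is no second check of them.

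**Figure D2:**
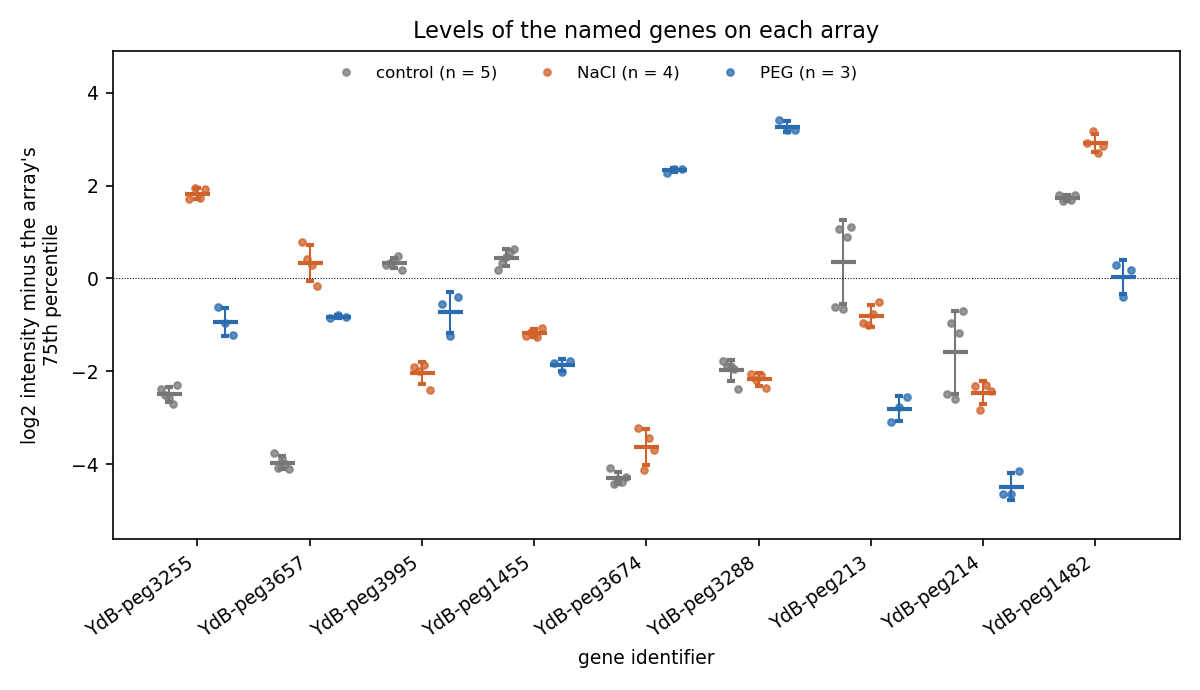
Log2 intensity minus the array's 75th percentile (vertical axis) of the genes named in the text (horizontal axis) on each array, with a dot per array and the group mean ± SD beside it, for control (n = 5), NaCl (n = 4) and PEG (n = 3). YdB-peg3674 stands at 2.33 in PEG and at -4.29 in control, and the control values of YdB-peg213 spread over an SD of 0.91.

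The third comparison set matric against solute stress directly. YdB-peg3674 was higher in PEG than in NaCl by 5.95 ± 0.17 (SE), or 61.8-fold (limma adjusted p = 4.45e-11), and YdB-peg3288 by 5.44 ± 0.13 (SE), or 43.4-fold (adjusted p = 2.27e-11). Against control, YdB-peg3288 changed in NaCl by -0.19 ± 0.12 (SE, adjusted p = 0.169). The 6 genes of its run were higher in PEG than in NaCl by a mean of 4.42. YdB-peg1482 was lower in PEG, with a difference of -2.88 ± 0.15 (SE, adjusted p = 2.52e-08), having changed by 1.17 in NaCl and by -1.71 in PEG against control. YdB-peg3255 differed by -2.75 ± 0.14 (SE, adjusted p = 1.81e-08), since it rose by 1.56 ± 0.13 (SE) in PEG and by 4.31 in NaCl.

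In PEG against NaCl limma called 4198 genes, 907 higher and 3291 lower, of which 59 were at least 2-fold higher in PEG and 648 at least 2-fold lower. The median gene differed by -0.34, and relative to it 228 genes were at least 2-fold higher and 231 at least 2-fold lower. Relative to the median gene, YdB-peg3674 differed by 6.29, YdB-peg3288 by 5.78, YdB-peg1482 by -2.54 and YdB-peg3255 by -2.41. The median difference was -0.77 in the 1587 dimmest genes and 0.16 in the 1587 brightest. These values and counts are therefore not relative to genes of like level. The share of higher genes was 21.6%, against 45.4% with median centring (1710 higher, 2060 lower), 50.8% with quantile normalization (1358 higher, 1316 lower) and 29% with normexp (1006 higher, 2465 lower). No slide held both stresses, and with the slide as a block 2434 genes were called, 440 higher and 1994 lower. Named genes then differed by 5.89 (YdB-peg3674), 5.13 (YdB-peg3288), -2.88 (YdB-peg1482) and -2.76 (YdB-peg3255). Between the control arrays of the slides limma called 0 genes, with 174 at an unadjusted p under 0.05. With only 3 control arrays on slide 1 and 2 on slide 2, this does not exclude differences between the slides.

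Under both stresses 408 genes were called higher and 342 lower, so that 750 changed in the same direction, and 438 changed in opposite directions (308 higher in NaCl and lower in PEG, 130 the reverse). At least 2-fold changes under both were shared by 32 genes that rose and 29 that fell. All of these kept their directions and calls under median centring, quantile normalization and normexp. Genes picked for called changes of at least 2-fold in these data were likely to keep them. A run of 4 genes rose by a mean of 3.00 in NaCl and 2.38 in PEG, and the run of YdB-peg3657 rose by means of 3.86 and 2.74. In the run of YdB-peg1455 the mean changes were -1.40 and -2.02. At least 2-fold changes in opposite directions were found in 7 genes. In 3 of these, YdB-peg1482 among them, NaCl was higher and PEG lower. The other 4 form a run with mean changes of -1.16 in NaCl and 1.18 in PEG. Of the 7, 6 kept both calls and directions after quantile normalization and 6 after normexp.

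Since the 2 comparisons share the control arrays, these counts were set beside several references. Independent lists of the same sizes would share 373 higher and 180 lower genes, and hold 537 higher in NaCl and lower in PEG and 125 the reverse. Across genes, which are not independent replicates, the 2 changes had a Pearson r of 0.27 and a covariance of 0.063, whereas simulated unchanged groups gave an r of 0.41 and a covariance of 0.008. The difference of covariances was 0.055. With the control arrays split between the comparisons, the median over 20 assignments was 508.5 genes in the same direction (470 to 531), 209.5 in opposite directions (176 to 329) and an r of 0.24. With the control arrays of its own slide for each stress, 531 genes changed in the same direction and 280 in opposite directions. Each comparison then had fewer control arrays than in the main fit, so fewer calls in either direction were likely. The count of opposite directions, 438 with all control arrays, also depended on the scaling, with 452 under median centring, 320 with normexp and 246 after quantile normalization.

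**Figure D3:**
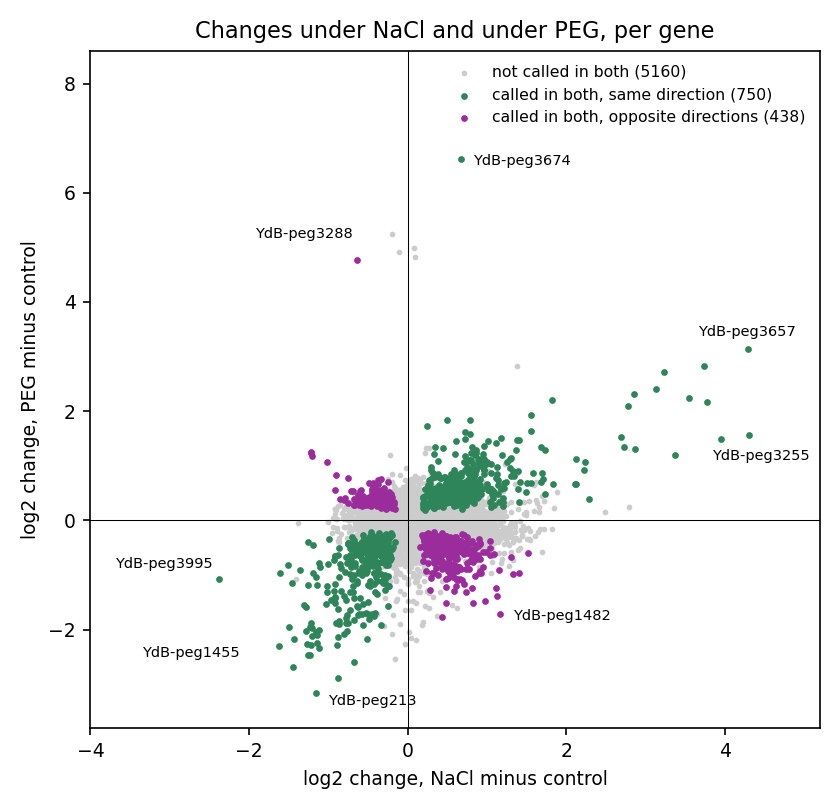
Log2 change in NaCl minus control (horizontal axis) against log2 change in PEG minus control (vertical axis), with a dot per tested gene, for genes called in both comparisons in the same direction (750), in opposite directions (438) and the rest. YdB-peg3674 and YdB-peg3288 stand at 6.62 and 5.25 on the PEG axis and at 0.67 and -0.19 on the NaCl axis, while YdB-peg3657 is high on both.

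Changes followed the order of the identifiers. Of the genes changed at least 2-fold, 59 (18.8%) lay in 17 runs in NaCl against control, 115 (45.1%) in 27 runs in PEG against control and 144 (20.4%) in 38 runs in PEG against NaCl. When identifiers were shuffled 1000 times, the highest numbers of genes in runs were 13, 6 and 52. Across genes, the changes of genes with consecutive numbers correlated with an r of 0.45 in NaCl against control, 0.51 in PEG against control and 0.51 in PEG against NaCl. At a distance of 10 numbers the r was 0.07, 0.02 and 0.10.

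**Figure D4:**
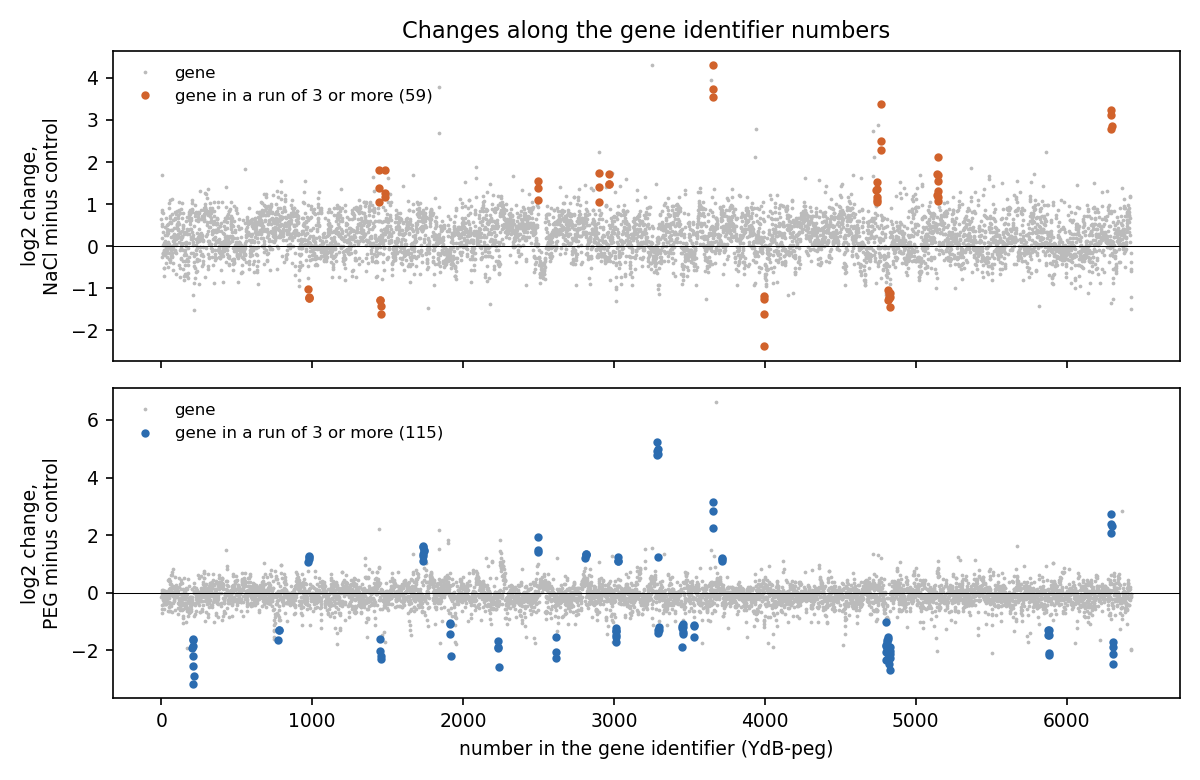
Log2 change (vertical axes) of each tested gene against the number in its YdB-peg identifier (horizontal axis), in NaCl minus control above and PEG minus control underneath, with the genes in runs of at least 3 in colour. The 59 coloured genes in NaCl and the 115 in PEG stand in narrow columns, among them the 6 genes around YdB-peg3288.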

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

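The probe DCP_22_4, which carries no bacterial identifier, was higher in NaCl than in control by 0.37 log2, with its lowest NaCl value at -4.5 and its highest control value at -4.51. Among 29 pairs of such a probe and a stress tested, it was the only 1 with all arrays of the stress above all control arrays. Its rise was no larger than that of dim genes. Those at a median control level of -4.29 rose by medians of 0.38 to 1.17 in the NaCl arrays. In 26 sets of control or NaCl values, from the named genes and the arrays' intensity measures, 0 arrays stood apart by Dixon's criterion.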

How the results depend on the processing

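Chosen only after the data were seen were normexp on the median spot signal, the fits within a slide, the fit without both NaCl replicates 1 and 3, and the own-slide controls. The 12 named changes gave 308 values under the alternatives, and 308 kept their direction and their call. These genes were picked for the largest changes, so keeping direction and call was likely, and their sizes did move. With normexp, YdB-peg214 changed by -1.77 in PEG against control, where the main fit gave -2.89. YdB-peg3674 changed there by 5.68 with normexp and by 6.62 in the main fit. Counts in PEG against control stayed between 1492 and 2259 genes, within 1.5 times the reported count. Genes changed by both stresses in the same direction (750) ranged up to 972 and down to a median of 508.5 over the splits of the control arrays, of which the lowest gave 470. Opposite changes (438) fell to 209.5 with split controls, 246 with quantile normalization, 280 with the slide block and 292 in the authors' table. The own-slide controls amount to the same fit as the slide block and gave the same counts. Split controls leave fewer control arrays per comparison, so fewer calls in either direction were likely. Other counts moved as well. Some fits had fewer arrays or genes, and the cause of the moves was not tested.

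In NaCl against control (3891 genes), the authors' table, with 5497 genes, gave 2535 genes (1169 higher, 1366 lower), the fit without both NaCl replicates 1 and 3 gave 2349, and slide 2 alone gave 2110. Genes changed at least 2-fold (314) were 126 with normexp, 164 with quantile normalization, 156 in the authors' table and 161 without both NaCl replicates. Leaving out 1 array gave 216 to 510 of them, and without NaCl replicate 2 there were 510, 467 higher and 43 lower. Over these fits all called genes ranged from 3329 to 4035.

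In PEG against NaCl (4198 genes), quantile normalization gave 2674 genes, the table of the authors gave 2548 genes and the slide block 2434. Genes changed at least 2-fold (707) were 189 with normexp, 227 with quantile normalization, 458 with median centring, 219 in the authors' table and 352 without both NaCl replicates. Leaving out 1 array gave 509 to 934. Genes in runs, 144 here, ranged from 67 to 241, and in NaCl against control (59) from 39 to 94. They did not always follow the number of genes past 2-fold. In PEG against NaCl the slide block gave 693 such genes and 166 in runs. In NaCl against control quantile normalization gave 164 such genes and 59 in runs.

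The replicate numbers do not pair the arrays: 6 of 10 same-number pairs correlated above 0.1 (-0.13 to 0.20), and in 6 of 20 pairs of an array and another group the best correlation was with its own number. With the replicate block, 3607, 1535 and 4058 genes were called in NaCl against control, PEG against control and PEG against NaCl, and 565 changed by both in the same direction. Genes changed at least 2-fold then numbered 350, 256 and 812. The scan batches coincided with the slides. The planned normexp on the mean spot signal, the gene list tests and their alternatives were not run. Dim genes limit the rest, since the lowest percentile of spots lay at 20.78 to 62.22 in NaCl, 15.87 to 23.32 in control and 7.258 to 17.06 in PEG.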

Other observations

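Tests chosen only after their results were seen were the one with probes of no bacterial identifier, the shuffled identifiers, the PEG-high genes in control replicate 3 and the unadjusted counts of the splits. The genes low in control replicate 3 were themselves found by looking at the largest control SDs.

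The 5 identifiers of the form YdB-rna, whose kind of RNA the files do not state, were higher in PEG than in control by 0.41 to 0.86 log2, and limma called 4 of them. In NaCl limma called 0 of the 5, and 0 had an unadjusted p under 0.05, with changes of 0.11 to 0.30. With median centring the PEG changes were 0.47 to 0.92 and with normexp 0.37 to 0.63, and limma called 4 under each. After quantile normalization the PEG changes were -0.20 to 0.31 and limma called 0 of them, also at an unadjusted p under 0.05 (0). Of the genes tested, 851 are not in the authors' table. Their median level was -3.89 against -1.16 for the others, and 738 of them were called higher in NaCl than in control and 2 lower.

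In control replicate 3, 24 genes lay at least 2-fold below all other control arrays, against 0 to 5 genes for each of the other control arrays. Their identifiers fall mostly into a stretch of 10 genes and another of 6, the latter within the run of YdB-peg213. They lay at a median of -1.98 log2 from the other control arrays, close to the PEG arrays (-1.67) and unlike the NaCl arrays (-0.08). In PEG against control 10 of them were called lower with control replicate 3 and 22 without it. In NaCl against control 3 were called lower without it. Genes picked as low in control replicate 3 were likely to gain calls when it was left out. RNA of a PEG culture in this sample is argued against, since 15 genes at least 4-fold higher in PEG differed in control replicate 3 by a median of 0.09, and a damaged area of the slide by a distance between probes 1.16 times that of random genes. A candidate explanation is that these genes vary between cultures by a condition that PEG also changes, a hypothesis that was not tested.

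More genes were higher than lower in NaCl with the 75th percentile as the scale. The excess depended on the scale, since 51.5% of called genes were higher under median centring, which evens out the directions by construction. In each NaCl array the median change fell with gene level and passed 0 near the level used as the scale. In NaCl replicates 1 and 3 it was 0.051 and 0.053 in genes at a control level of -0.77. At a control level of -0.16 it was -0.096 and -0.074. The share of higher genes thus depends on the level chosen as the scale, and the right choice stays open. A factor for a whole array moves all genes alike, so it leaves the dependence on gene level (medians of 0.64 in the 1587 dimmest genes and -0.16 in the 1587 brightest), for which other possible explanations were tested. A constant added to every gene misfitted 10 level groups of genes in NaCl replicates 1 and 3 by 0.115 and 0.104 log2. These values are over the limit of 0.05 set beforehand. A straight line in log level misfitted the groups a little less (0.1 and 0.091), also over that limit. Gene values are log2 means over probes, in which a constant added per spot need not follow the fitted curve. The misfit therefore does not decide on such a constant. The fitted constants were 8.96% and 7.55% of the 75th percentile, which lay at 1694 and 1094. Negative control spots had medians of 7.057 and 7.007 in these arrays, inside the range of the control arrays (6.869 to 8.519). This argues against a constant of the fitted size on all spots, negative controls included. A signal confined to the gene probes is not covered. Probes without a bacterial identifier rose by a median of 0.32 against 0.99 in genes of like level, a median difference of -0.5, which argues against unspecific signal as the whole cause. A different RNA composition under NaCl and a different labelling of these arrays both stay open, untested.

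Of the genes changed at least 2-fold, 18.8% in NaCl against control, 45.1% in PEG against control and 20.4% in PEG against NaCl lay in runs of consecutive identifiers. The distance between probes of consecutive genes was 1.02 times that of random genes, which argues against neighbouring spots, and shuffled identifiers gave at most 13 genes in runs in NaCl against control, where 59 were seen. A possible explanation of these runs is that consecutive numbers mark neighbouring genes read as 1 transcript. Whether they lie side by side on one strand was not tested.

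Chance division of the arrays, taken without regard to slide, is argued against for each count of changed genes. The splits exchanged arrays across the slides, so they do not tell stress from slide. Splits kept within a slide were not run. In NaCl against control, only 1 of 100 splits of the arrays, the real one, gave 3891 genes by limma (highest other 2471) and only 1 gave 314 changed at least 2-fold (highest other 165). At an unadjusted p under 0.05 the real split gave 4165 and 317, and the highest others 3331 and 173. For PEG against control, 1 of 56 splits gave 1982 and 255 genes, and the other splits gave at most 0 of either by limma. At an unadjusted p under 0.05 the real split gave 2614 and 262, and the highest others 957 and 96. In PEG against NaCl, 1 of 35 splits gave 4198 (highest other 3324) and 707 (highest other 525). Here the real split is also the split by slide, so its being the largest cannot tell stress from slide. With the slide as a block, 2434 genes were called. At an unadjusted p under 0.05 the real split gave 4400 and 707, and the highest others 3786 and 536.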
